A study of Mus musculus with 32 samples.

How the data were processed

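Small RNA was sequenced from the mesenteric arteries of 32 male C57BL/6J mice aged 10 to 12 weeks. The mice received angiotensin II (Ang II, 1000 ng/kg/min under the skin) or a sham operation for 7 or 14 days. Each of the 4 groups held 8 libraries, and the labels give 10 mice per group and 1 µg of RNA per library. Libraries were made with a TruSeq small RNA kit and sequenced on a HiSeq instrument. The submitters' notes name bcl2fastq 1.8.4, FastQC, STAR 2.3.1, R 3.2.3, edgeR 3.6.8 and the mouse build mm10, without stating what each tool did. The annotation and the treatment of reads with several mapping places were not stated.

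The table deposited by the authors holds 1 signal value per miRNA row and library, without a stated unit. Every value was a whole multiple of its library's smallest step, within a tolerance of 0.001 read. The deposited signal therefore corresponds to whole reads divided by a library-specific effective size and scaled as RPM (reads per M, where M is mega) would be. Column totals ran from 0.727 to 1.67 M, so the authors' scaling was more than division by the library total. These values are called normalised RPM, or RPM, below. All 32 columns matched a sample by group and mouse number.

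The table had 1722 rows, of which 364 were 0 in every library. It had 1403 distinct names, and 114 names had more than 1 row. The row with the highest mean was kept for each name, rows that were 0 throughout were dropped, and names with equal reads in every library were merged, which left 1030 distinct rows. Of these, 34 carried joint names such as miR-486-5p/miR-3107-5p, and 128 carried names of the form Novel_y_2, for which the files give no location. Rows with a mean of at least 1 RPM over the 32 libraries were tested, which left 543. Some tested rows were near copies of each other, and they are reported as uncertain where they are named.

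Recovered reads in distinct rows ran from 11.4 to 18.8 M per library. All rows together held 14.0 to 24.6 M. A limit of 3 reads stood at 0.0888 to 0.351 RPM, depending on the library. Such limits cover counting error alone, since PCR reads without molecular identifiers are not independent molecules. The deposited values were normalised, so the fallback test fixed before the data were examined was used. It was limma-trend (limma 3.58.1, R 4.3.3) on log2(value + 1), with 1 model for the 4 groups. The comparisons were Ang II against sham at 7 and at 14 days, their difference (the interaction), 14-day sham against 7-day sham, and the average Ang II effect over both times. Calls were made at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Fold changes are on the log2(value + 1) scale and understate changes of miRNAs with few reads. Errors of log2 fold changes are standard errors (SE), and errors of group means are standard deviations (SD) over 8 libraries.

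Lists of miRNAs were fixed before the data were examined. They covered the Dlk1-Dio3 cluster, contractile smooth muscle, striated muscle, endothelium, leukocytes, red blood cells, neurons, adipose tissue, epithelium, pancreatic acinar cells, fibrosis and remodelling, the miR-29 family, miR-132/miR-212, miR-221/miR-222, the miR-17 clusters, the miR-322/miR-503 cluster, NF-kB induced miRNAs, the let-7 family, the miR-30 family, the miR-23/miR-27/miR-24 clusters, hypoxia and the H19/Igf2 locus. The 20 lists with at least 2 tested members were tested with camera, with the correlation between members estimated from the data, and adjusted together. The mean log2 value of each list per library, here called its score, was compared by exact two-sided permutation tests, adjusted over 42 tests. The difference of the list scores' Ang II effects between the times was tested by permutation with 100000 resamples, adjusted over 21 lists. Both tests of list scores were chosen after the data were seen.

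The rule for named miRNAs was fixed before the data were examined. It took, per Ang II comparison, up to 12 called miRNAs with the largest rise and 12 with the largest fall, at a mean of at least 10 RPM. With fewer than 5 called, it took the 5 with the smallest p. It also took up to 4 members per list by smallest p, and always miR-431-5p, miR-21a-5p, miR-143-3p, miR-145a-5p, miR-126-3p, miR-132-3p and miR-155-5p. For the interaction and the average effect it took the 5 with the smallest p, and for abundance the 5 with the highest share.

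The alternatives fixed before the data were examined were edgeR's RLE size factors, library totals alone, no filter, and a mean of at least 10. Others were a DESeq2 1.42.0 Wald test, limma-voom with sample quality weights, a fit to the compared groups alone, and the mouse-number series (the leading 26, 27, 28 or 30) as a term. Pseudocounts of 0.5 and 10, each library left out in turn, camera with a preset correlation of 0.01, and fry completed them. Scaling and count-based tests used the recovered reads. Alternatives chosen after the data were seen were an edgeR 4.0.16 quasi-likelihood test, TMM factors, and a term for 2 classes of libraries. Each class alone, omission of the 2 mice of mouse-number series 30, and every row kept, copies included, were also chosen then.

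Positions came from the GRCm38 annotation, the assembly that mm10 names. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The pipeline was tested on simulated data, with each miRNA drawn independently and 200 of 543 miRNAs changed in the 14-day comparison. It recovered 16% of those changed 1.25-fold, 38% at 1.5-fold, 82% at 2-fold and 94% at 3-fold. It made 118 calls, of which 3 were false, and 0 calls with limma in the unchanged 7-day comparison.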

Results

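Mesenteric arteries, the vessels that feed the gut and contribute to resistance to blood flow, were profiled for small RNA in 4 groups of 8 mice. The groups were 7-day sham, 7-day Ang II, 14-day sham and 14-day Ang II. Angiotensin II is a peptide hormone that raises blood pressure. The libraries held 11.4 to 18.8 M (mega) recovered reads in distinct rows. The mean was 15.3 ± 1.93 M in 7-day Ang II and 15.96 ± 0.778 M in 7-day sham (SD, n = 8 each, exact permutation p = 0.387). At 14 days it was 16.2 ± 2.41 M with Ang II and 14.7 ± 1.32 M in sham (SD, n = 8 each, exact permutation p = 0.131). Over all deposited rows, copies included, the 14-day difference was 3.06 M (n = 8 each, exact permutation p = 0.0452).

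The most abundant miRNA was miR-143-3p, which marks smooth muscle, with 46.9% ± 3.72 of the reads (SD, n = 32). It was followed by miR-10b-5p with 8.13% ± 2.97, miR-26a-5p with 6.04% ± 1.20, miR-10a-5p with 5.51% ± 0.771 and miR-30a-5p with 3.17% ± 0.783. The share of miR-143-3p was 45.0% ± 4.17 in 14-day Ang II and 46.4% ± 3.47 in 14-day sham (SD, n = 8 each, exact permutation p = 0.53). The libraries fell into 2 classes along the first principal component of the spread within groups, which held 35.6% of that variance. Class A had 19 libraries and class B had 13. Class A held 5 of the 7-day sham, 3 of the 7-day Ang II, 5 of the 14-day sham and 6 of the 14-day Ang II libraries. For the lists described at length and for several named miRNAs, values within each class are given below beside the pooled ones, and likewise within each mouse-number series (numbers that share their leading 26, 27 or 28) that held at least 3 libraries per arm.

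The first question was how Ang II altered arterial miRNAs after 7 days. The passenger strand miR-145a-3p, from the miR-143/miR-145 locus that is known for its high expression in contractile smooth muscle, was the 1 miRNA that changed. It fell from 896 ± 159 to 596 ± 142 RPM (SD, n = 8 each), a 0.658-fold level, and lay below the sham median in 8 of 8 libraries. Its log2 fold change was -0.60 ± 0.13 (SE), with an adjusted p of 0.0280. The hairpin lies on chromosome 18 at 61647825 to 61647894, outside annotated genes.

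The 7-day sham group was the highest of the 4 for miR-145a-3p, with 14-day sham at 604 ± 67.6 and 14-day Ang II at 560 ± 89.8 RPM (SD, n = 8 each). The call held in 12 of 16 other settings, and in 6 of 16 fits that left out a library. It ended with library totals alone, with the compared groups alone, and within class A or class B alone. The log2 fold change was -0.68 within class A and -0.50 within class B. It was -0.61 and -0.48 within the mouse-number series 27 and 28. With limma, 37 of 543 miRNAs had an unadjusted p under 0.05, against 27.2 by chance. limma-voom with quality weights called 10, 7 higher and 3 lower.

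Among the miRNAs next in order of p, none passed the test. They were miR-411-5p (log2 fold change 0.37, adjusted p = 0.253), miR-298-5p (0.57, adjusted p = 0.253), miR-673-5p (0.40, adjusted p = 0.324) and miR-540-3p (0.57, adjusted p = 0.324). Each lay above the sham median in 8 of 8 libraries. The profibrotic miR-21a-5p averaged 2828 ± 491 in sham and 4411 ± 1098 with Ang II (SD, n = 8 each, log2 fold change 0.62 ± 0.20 SE, adjusted p = 0.373). It lay above the sham median in 8 of 8 libraries. Its log2 fold change was 0.64 within class A, 0.57 within class B, 0.52 within series 27 and 0.75 within series 28. Its partner strand miR-21a-3p had a log2 fold change of 0.78 (adjusted p = 0.439). Values for miR-431-5p were 0.41 (adjusted p = 0.439), and for miR-132-3p 0.41 (adjusted p = 0.439). The log2 fold change of miR-145a-5p was -0.32 (adjusted p = 0.704), that of miR-126-3p was -0.20 (adjusted p = 0.756) and that of miR-155-5p was 0.07 (adjusted p = 0.958). Without 7-day sham replicate 4 the value of miR-155-5p was -0.004. The value of miR-143-3p was -0.04 (adjusted p = 0.995), and it was 0.01 with library totals alone.

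As groups, 0 of 20 lists passed camera at 7 days with an estimated correlation, 3 of them with an unadjusted p under 0.05. With a preset correlation 7 passed, and with fry 0 passed, 4 with an unadjusted p under 0.05. Those 7 were the Dlk1-Dio3 cluster, contractile smooth muscle, leukocytes, red blood cells, fibrosis and remodelling, the miR-29 family and miR-132/miR-212. The fibrosis and remodelling list (miR-21a, miR-199a, miR-199b and miR-214) had 7 of 7 members above 0, a median log2 fold change of 0.19 and an adjusted p of 0.102 with an estimated correlation. Its score was 7.77 ± 0.219 with Ang II and 7.43 ± 0.114 in sham (mean log2, SD, n = 8 each, exact permutation p = 0.000932, adjusted p = 0.0196), with 7 of 8 Ang II libraries above every sham library. Adjusted over the list alone, 2 of its members were higher. Its median was 0.49 within class A, 0.18 within class B, 0.42 within series 27 and 0.12 within series 28. The contractile smooth muscle list (miR-143 and miR-145) had 0 of 5 members above 0, a median of -0.32 and an adjusted p of 0.102 with an estimated correlation. Its score differed by -0.32 (n = 8 each, exact permutation p = 0.00606, adjusted p = 0.0364). Its median was -0.36 within class A, -0.11 within class B, -0.28 within series 27 and -0.50 within series 28.

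The Dlk1-Dio3 cluster, an imprinted region with 1 of the largest groups of mammalian miRNAs, had 47 of 58 members above 0 at 7 days and a median of 0.18 (adjusted p = 0.329 with an estimated correlation). Adjusted over the list alone, 0 members passed. Its median was 0.18 within class A, 0.22 within class B, 0.23 within series 27 and 0.04 within series 28. The other adjusted p values with an estimated correlation, with the medians, were as follows. Leukocytes had a median of 0.18 (adjusted p = 0.329), red blood cells 0.35 (adjusted p = 0.428), and miR-132/miR-212 0.25 (adjusted p = 0.329). The miR-29 family had -0.18 (adjusted p = 0.294), the miR-23/miR-27/miR-24 clusters -0.12 (adjusted p = 0.329), the miR-30 family -0.09 (adjusted p = 0.447) and endothelium -0.12 (adjusted p = 0.447). Medians of the remaining tested lists ran from -0.18 for neurons to 0.07 for the miR-17 clusters, with adjusted p values from 0.614 to 0.814. Between these limits lay striated muscle, adipose tissue, epithelium, pancreatic acinar cells, miR-221/miR-222, the miR-322/miR-503 cluster, NF-kB induced miRNAs and the let-7 family. The hypoxia list had 1 tested member, miR-210-3p, at 0.09, and the H19/Igf2 locus had 0.

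The second question was the same after 14 days of infusion. Here 35 of 543 miRNAs changed, 24 higher and 11 lower. The largest rises belonged to miR-144-5p and miR-451a, which are made together in developing red blood cells. They were followed by members of the Dlk1-Dio3 cluster, led by miR-434-5p, miR-431-5p and miR-337-5p. The miR-132-3p and miR-212-3p pair, made from 1 locus and known to be induced by growth and neuronal signals, rose as well. The falls included miR-203-3p, an epithelial miRNA, and miR-101a-3p, miR-181c-5p and miR-26b-5p.

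miR-144-5p rose from 31.8 ± 17.5 to 64.0 ± 20.9 RPM (SD, n = 8 each, 2.24-fold, log2 fold change 1.16 ± 0.36 SE, adjusted p = 0.0493). miR-451a rose from 587 ± 345 to 1044 ± 296 (1.98-fold, adjusted p = 0.0296). miR-434-5p rose from 46.1 ± 9.08 to 85.0 ± 31.7 (1.78-fold, log2 fold change 0.83 ± 0.17 SE, adjusted p = 0.00626). miR-431-5p rose from 16.2 ± 2.65 to 29.8 ± 9.44 (1.74-fold, log2 fold change 0.80 ± 0.15 SE, adjusted p = 0.00473). miR-132-3p rose from 18.3 ± 4.02 to 28.5 ± 5.55 (1.54-fold, adjusted p = 0.00931). miR-541-5p rose from 312 ± 52.3 to 473 ± 97.0 (log2 fold change 0.59 ± 0.12 SE, adjusted p = 0.00473). miR-203-3p fell from 89.0 ± 21.1 to 60.9 ± 8.68 (0.698-fold, adjusted p = 0.0174). In each of these 7, 8 of 8 Ang II libraries lay on the same side of the sham median. The 95% interval of the log2 fold change was 0.49 to 1.12 for miR-431-5p.

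**Figure D1:**
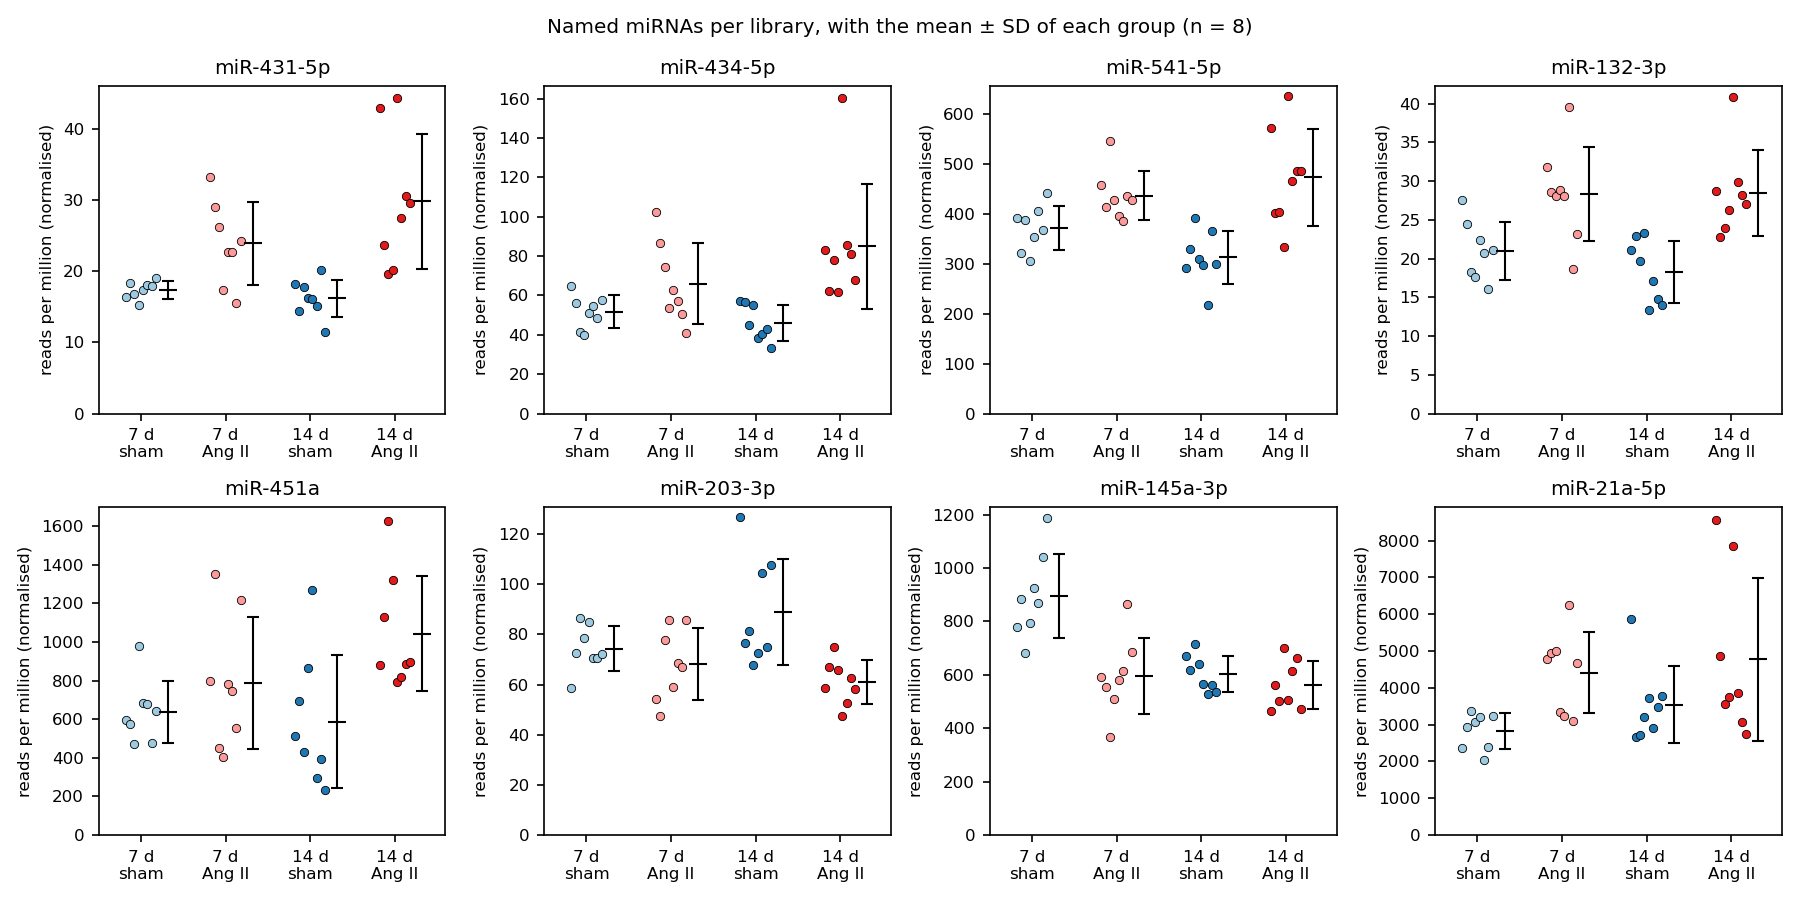
Normalised RPM of 8 miRNAs in each library, with points for libraries and bars for the group mean ± SD (n = 8 per group). At 14 days miR-431-5p averaged 29.8 with Ang II and 16.2 in sham, and at 7 days miR-145a-3p averaged 596 with Ang II and 896 in sham.

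Other rises were miR-337-5p (1.71-fold, adjusted p = 0.00682), miR-106b-3p (1.54-fold, adjusted p = 0.0241) and miR-140-5p (1.40-fold, adjusted p = 0.0265). Also higher were miR-300-3p (1.38-fold, adjusted p = 0.0493), miR-140-3p (1.36-fold, adjusted p = 0.0174) and miR-411-5p (1.35-fold, adjusted p = 0.0174). The list members miR-382-5p (1.68-fold), miR-212-3p (1.43-fold) and miR-199a-5p (1.34-fold) passed with adjusted p values of 0.00616, 0.0328 and 0.0174. Falls were found for miR-101a-3p and miR-101c (log2 fold change -0.41 each, adjusted p = 0.0403), miR-708-3p (0.737-fold, adjusted p = 0.0489), miR-181c-5p (0.790-fold, adjusted p = 0.0368) and miR-26b-5p (0.828-fold, adjusted p = 0.0493). The values of miR-101a-3p and miR-101c were nearly identical, so which of the pair changed is uncertain. Unplaced entries named Novel_y_30 (0.543-fold), Novel_y_47 (0.657-fold) and Novel_y_2 (0.725-fold) were also lower, with adjusted p values of 0.0493, 0.0296 and 0.0296. The miR-183/miR-96/miR-182 cluster was chosen after its values were seen. miR-96-5p fell to 0.607-fold (adjusted p = 0.0174), while miR-183-5p had a log2 fold change of -0.91 (adjusted p = 0.336) and miR-182-5p -0.60 (adjusted p = 0.225).

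The named hairpins were placed on GRCm38. Mir431 lies on chromosome 12 at 109590447 to 109590537 and Mir434 at 109594506 to 109594599, both opposite an exon of Rtl1. Mir541 lies at 109742409 to 109742498 in an intron of the noncoding gene Mirg. Mir132 lies on chromosome 11 at 75173682 to 75173747 and Mir212 at 75173388 to 75173478, both in an intron of 1700016P03Rik. Mir144 at 78073005 to 78073070 and Mir451a at 78073170 to 78073241 are neighbours on chromosome 11. Mir203 lies on chromosome 12 at 112130880 to 112130955, outside the cluster.

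The 14-day count moved with the test and the scaling. With limma, 140 miRNAs had an unadjusted p under 0.05, against 27.2 by chance. edgeR called 46, 25 higher and 21 lower. DESeq2 called 63, 32 higher and 31 lower, of which 33 were among the 35. Library totals alone moved the median log2 fold change of all miRNAs to 0.23 and gave 22 higher and 1 lower, so each rise or fall here is relative to the authors' scaling. A fit to the compared groups alone called 3, all higher, namely miR-434-5p, miR-431-5p and miR-337-5p, and limma-voom with quality weights called 16. With no filter on low values 17 were called, 15 higher and 2 lower. Within class A alone (6 Ang II and 5 sham libraries) and class B alone (2 and 3), limma called 0, with 107 and 105 at an unadjusted p under 0.05, while a term for the class gave 80. The count was 21 without 14-day Ang II replicate 3. It was 23 without 14-day Ang II replicate 5 or 7, or 14-day sham replicate 5 or 8.

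miR-431-5p and miR-434-5p passed in 14 of 16 other settings and in 16 of 16 fits that left out a library. Less firm were the calls of miR-26b-5p, Novel_y_30, miR-144-5p, miR-300-3p, miR-708-3p, miR-181c-5p and the miR-101a-3p and miR-101c pair, which passed in 3, 4, 5, 5, 6, 8 and 9 of those 16 fits. In the 16 other settings they passed in 7, 5, 4, 7, 7, 10 and 8, in the same order. There miR-451a passed in 10 and miR-203-3p in 11. The log2 fold change of miR-203-3p ran from -0.57 to -0.25 over those settings. With library totals alone the log2 fold change of miR-26b-5p was -0.002 (adjusted p = 0.994). The log2 fold change of miR-431-5p was 0.73 within class A, 0.99 within class B and 0.76 within series 26. For miR-434-5p these values were 0.74, 0.91 and 0.78, and for miR-541-5p 0.60, 0.59 and 0.59. For miR-451a they were 0.96, 1.03 and 0.87, for miR-132-3p 0.47, 0.83 and 0.52, and for miR-203-3p -0.57, -0.41 and -0.47. The other series had too few libraries of 1 arm at 14 days.

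The tested members of the Dlk1-Dio3 cluster come from 39 hairpins on chromosome 12 between 109571990 and 109743795, a span of 171.8 kb. At 14 days 57 of 58 members were above 0, with a median log2 fold change of 0.40. Over all miRNAs 14 members rose, and 27 were higher adjusted over the list alone. The most abundant member, miR-127-3p, was 1.08-fold (limma adjusted p = 0.772), with 3 of 8 Ang II libraries above the sham median. The 58 include miR-299a-3p and miR-299b-3p, whose values were nearly identical. The study is known to have singled out miR-431 from these libraries, so the list is not independent evidence of its direction. camera gave an adjusted p of 0.155 with an estimated correlation (p = 0.00777 before adjustment), and the preset correlation and fry both passed. The cluster score was 3.39 ± 0.330 with Ang II and 2.99 ± 0.101 in sham (mean log2, SD, n = 8 each, exact permutation p = 0.00140, adjusted p = 0.0196), with 8 of 8 Ang II libraries above the sham median. Of the Ang II scores, 5 of 8 lay above every sham library. Replicates 5, 1 and 3 were highest with 3.951, 3.781 and 3.544, and the other Ang II libraries ran from 3.059 to 3.331. The median log2 fold change was 0.37 within class A (54 of 58 above 0), 0.56 within class B (55 of 58) and 0.53 within series 26 (58 of 58).

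**Figure D2:**
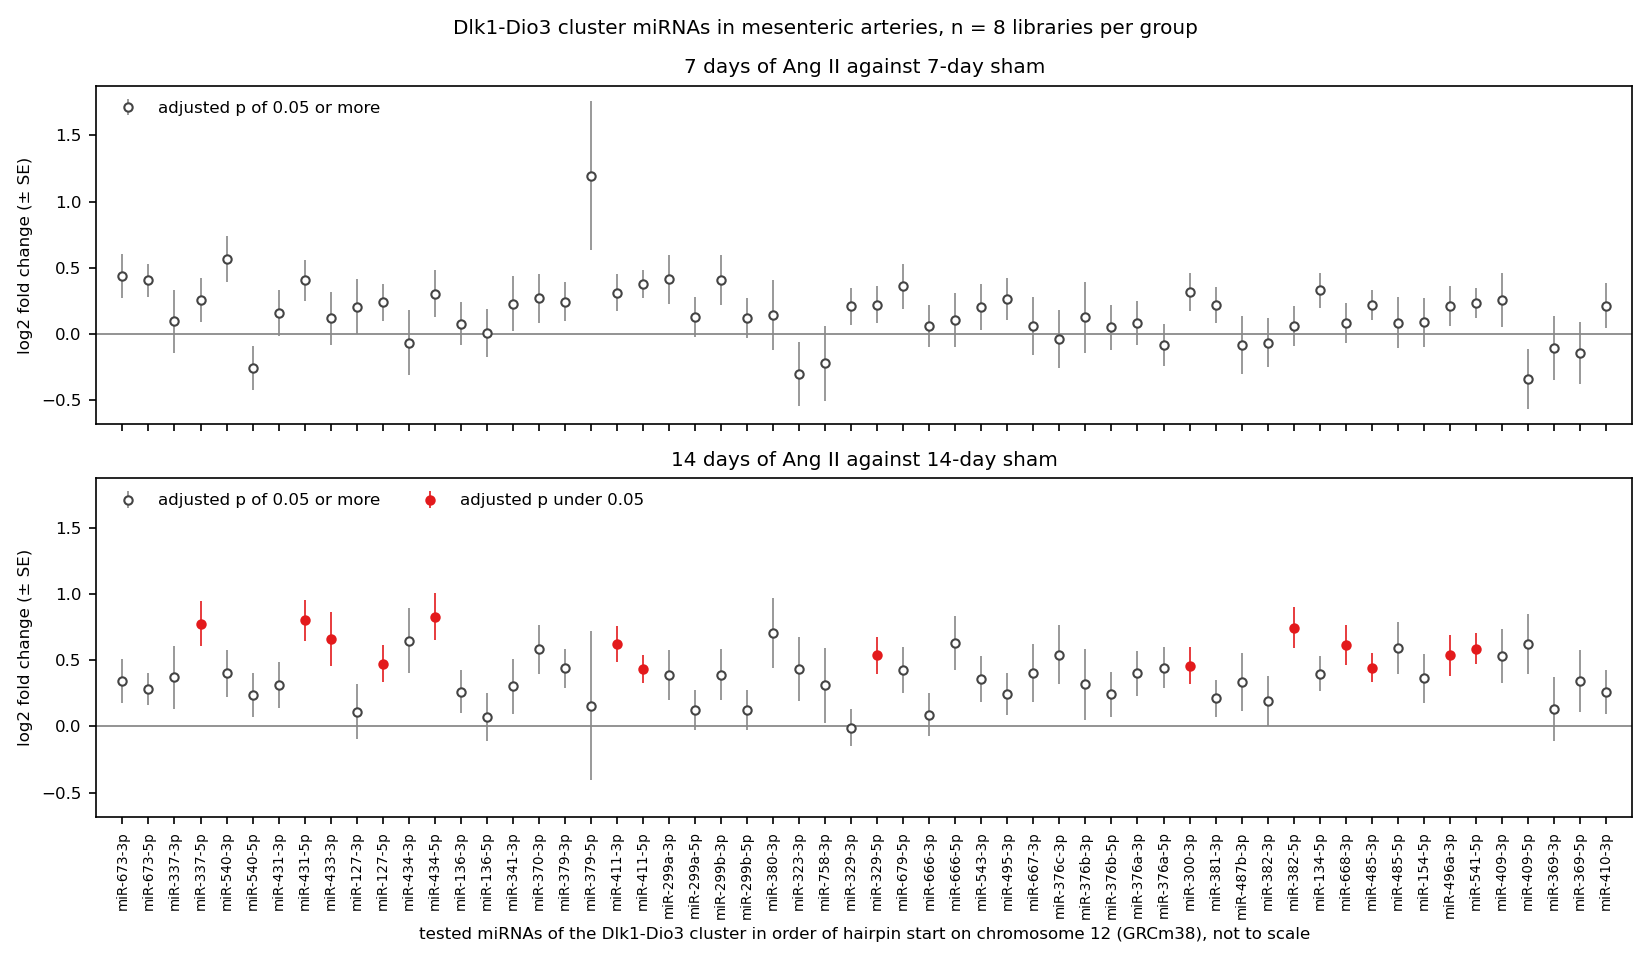
Log2 fold change (Ang II against sham) ± SE of the tested Dlk1-Dio3 miRNAs in the order of their hairpins on chromosome 12, at 7 and 14 days (n = 8 per group). Red marks an adjusted p under 0.05, which 14 of the 58 members reached at 14 days and 0 at 7 days; 57 of 58 members lay above 0 at 14 days.

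Red blood cell miRNAs (miR-144, miR-451a and miR-486) had 5 of 5 members above 0 at 14 days and a median of 0.99. Of these, 2 rose, and 5 were higher adjusted over the list alone (camera adjusted p = 0.234 with an estimated correlation). Their score was 8.12 ± 0.264 with Ang II and 7.20 ± 0.710 in sham (SD, n = 8 each, exact permutation p = 0.00404, adjusted p = 0.0339). The median was 0.96 within class A, 1.03 within class B and 0.87 within series 26. miR-144-3p had a log2 fold change of 1.00 (adjusted p = 0.0698), and miR-486-5p/miR-3107-5p 0.80 (adjusted p = 0.164).

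Epithelial miRNAs (such as the miR-200 family) had 0 of 12 members above 0 at 14 days, with a median of -0.73. None was called over all miRNAs, and 5 were lower adjusted over the list alone (camera adjusted p = 0.234 with an estimated correlation). The score was 6.27 ± 0.202 with Ang II and 6.96 ± 0.678 in sham (SD, n = 8 each, exact permutation p = 0.00544, adjusted p = 0.0364). The median was -0.59 within class A, -0.97 within class B and -0.68 within series 26. miR-141-3p averaged 1557 ± 779 in sham and 796 ± 231 with Ang II (SD, n = 8 each, log2 fold change -0.85, adjusted p = 0.0510). Its log2 fold change was -0.60 within class A, -1.05 within class B and -0.47 within series 26. Values for miR-200a-5p and miR-200c-3p were -0.76 (adjusted p = 0.0586) and -0.69 (adjusted p = 0.0705).

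**Figure D3:**
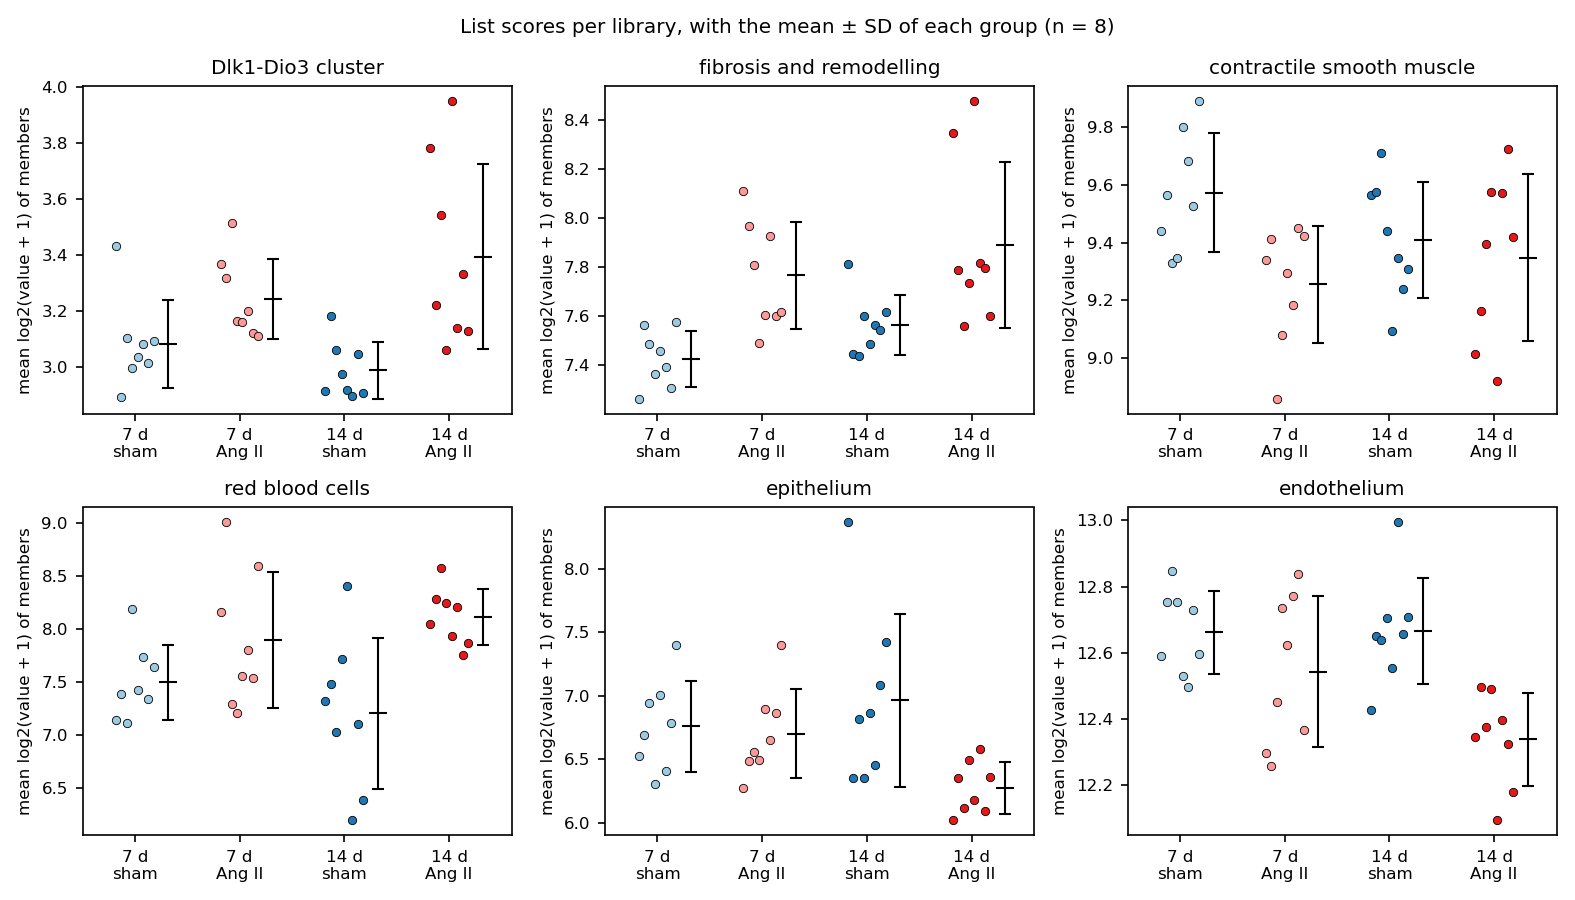
Mean log2(value + 1) of 6 miRNA lists in each library, with points for libraries and bars for the group mean ± SD (n = 8 per group). At 14 days the epithelium score averaged 6.27 with Ang II and 6.96 in sham, and the Dlk1-Dio3 score 3.39 and 2.99.

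The miR-132/miR-212 list had 4 of 4 members above 0 at 14 days, a median of 0.52, 2 that rose and 4 higher adjusted over the list alone (camera adjusted p = 0.234 with an estimated correlation). Its score differed by 0.53 (n = 8 each, exact permutation p = 0.00326, adjusted p = 0.0339), and its median was 0.43 within class A, 0.60 within class B and 0.44 within series 26. Fibrosis and remodelling had 7 of 7 members above 0 and a median of 0.39, with 1 that rose, miR-199a-5p (camera adjusted p = 0.256 with an estimated correlation). Its score differed by 0.33 (n = 8 each, exact permutation p = 0.0103, adjusted p = 0.0539), and its median was 0.27 within class A, 0.55 within class B and 0.35 within series 26. In this list miR-21a-5p had a log2 fold change of 0.36 (adjusted p = 0.260) and miR-214-3p 0.41 (adjusted p = 0.117). The value of miR-21a-5p was 0.23 within class A, 0.82 within class B and 0.66 within series 26. It ran from 0.22 to 0.47 with 1 library left out.

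Endothelium, represented by both strands of miR-126, had a median of -0.33 at 14 days (camera adjusted p = 0.297 with an estimated correlation). Its score was 12.3 ± 0.140 with Ang II and 12.7 ± 0.161 in sham (SD, n = 8 each, exact permutation p = 0.000622, adjusted p = 0.0196). The median was -0.37 within class A, -0.22 within class B and -0.30 within series 26. miR-126-5p had a log2 fold change of -0.53 (adjusted p = 0.0901), and from -0.561 to -0.261 over the other settings. For miR-126-3p the log2 fold change was -0.12 (adjusted p = 0.480), and 0.15 with library totals alone. The score was tested with the authors' scaling only. The estimated correlation between the strands was -0.543, and averaging strands that vary against each other narrows the spread of the score. Leukocyte miRNAs had a median of 0.34 (adjusted p = 0.297; 0.18 within class A, 0.56 within class B and 0.31 within series 26), with miR-142-5p at 0.49 (adjusted p = 0.107) and miR-223-5p at 0.39 (adjusted p = 0.0825). The miR-30 family had 0 of 9 members above 0, a median of -0.30 and 7 lower adjusted over the list alone (adjusted p = 0.234 with an estimated correlation). Its median was -0.22 within class A, -0.30 within class B and -0.28 within series 26.

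Contractile smooth muscle had a median of -0.12 at 14 days (adjusted p = 0.751), which was 0.15 with library totals alone. In it miR-143-3p had -0.32 (adjusted p = 0.336), and from -0.346 to -0.045 over the other settings. miR-145a-5p had -0.01 (adjusted p = 0.952), which was 0.26 with library totals alone. The same scaling turned the medians of striated muscle from -0.21 to 0.05, of the miR-29 family from -0.23 to 0.04 and of the miR-23/miR-27/miR-24 clusters from -0.08 to 0.19. Their adjusted p values were 0.613, 0.544 and 0.710. miR-155-5p, an inflammation-linked miRNA, had 0.35 (adjusted p = 0.168), and the NF-kB induced list also 0.35 (adjusted p = 0.613). Medians were -0.34 for pancreatic acinar cells (adjusted p = 0.613), 0.12 for miR-221/miR-222 (adjusted p = 0.544) and 0.17 for the miR-17 clusters (adjusted p = 0.544). They were 0.10 for neurons with a mean of -0.01, 0.00 for adipose tissue with a mean of -0.05, 0.00 for the miR-322/miR-503 cluster with a mean of -0.03 and 0.01 for the let-7 family. These 4 had adjusted p values of 0.913, 0.743, 0.836 and 0.893, and the last 3 medians changed sign with the mouse-number series as a term. The hypoxia miRNA miR-210-3p stood at -0.12, and 0 members of the H19/Igf2 locus were tested. Over the 20 lists, 0 passed camera with an estimated correlation (3 with an unadjusted p under 0.05), 7 with a preset correlation and 8 with fry.

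The third question was whether the response to Ang II differed between the times. With limma, 0 of 543 miRNAs passed, and 25 had an unadjusted p under 0.05, against 27.2 by chance. edgeR, DESeq2 and limma-voom also called 0. The smallest p values belonged to miR-382-5p (difference in log2 fold change 0.69 ± 0.22 SE), miR-409-5p (0.96), miR-29a-5p (0.48), miR-145a-3p (0.49) and Novel_x_29 (1.10), each with an adjusted p of 0.804. For miR-431-5p the difference was 0.40 with a 95% interval from -0.05 to 0.84, so a larger effect at either time was not shown. camera with an estimated correlation called 0 of 20 lists for the interaction (1 with an unadjusted p under 0.05, smallest adjusted p = 0.570), and fry called 0. With a preset correlation the Dlk1-Dio3 cluster, epithelium and the miR-30 family passed. Of 21 list scores, 0 differed between the times after adjustment. The smallest p was that of epithelium (difference -0.63, permutation p = 0.0428, adjusted p = 0.486), and for the Dlk1-Dio3 cluster the difference was 0.24 (permutation p = 0.0948, adjusted p = 0.486).

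Across the 543 miRNAs, which are not independent replicates, the 7-day and 14-day log2 fold changes correlated with r = 0.246 and rho = 0.418. The jackknife SE of r was 0.381 and the range with 1 library left out was 0.074 to 0.364. Of the 543, 372 had the same sign at both times. Of the 36 miRNAs called at either time, 36 had the same sign at the other time, and 0 were called at both, against 0.0203 by chance among those lower.

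The average effect over both times used all 32 libraries, and 40 miRNAs changed, 29 higher and 11 lower. The smallest p values belonged to miR-431-5p (1.52-fold, log2 fold change 0.60 ± 0.11 SE, adjusted p = 0.00192), miR-411-5p (1.32-fold, adjusted p = 0.00192) and miR-132-3p (1.43-fold, adjusted p = 0.00270). Next came miR-541-5p (1.33-fold, adjusted p = 0.00285) and miR-411-3p (1.38-fold, adjusted p = 0.00436). The Dlk1-Dio3 cluster supplied 20 of the 29 rises (camera adjusted p = 0.163 with an estimated correlation). For the average effect camera called 0 of 20 lists with an estimated correlation (4 with an unadjusted p under 0.05), 8 with a preset correlation, and fry called 9. miR-21a-5p also rose on average (1.40-fold, adjusted p = 0.0342), as did miR-199a-5p (1.24-fold, adjusted p = 0.0137), both members of the fibrosis list and chosen here after their values were seen. miR-21a-5p passed in 23 of 32 fits that left out a library. DESeq2 called 68, 48 higher and 20 lower, and edgeR called 55, 40 higher and 15 lower. Library totals alone, which moved the median of all miRNAs from -0.03 to 0.12, gave 23 higher and 0 lower. Within class A alone 12 were called and within class B alone 0 (115 at an unadjusted p under 0.05), while a term for the class gave 129.

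The last comparison asked whether the sham groups differed between the times. These groups differed in mouse-number series as well as in time, and the parts of series and time could not be fully told apart. With limma, 0 of 543 miRNAs passed, and 18 had an unadjusted p under 0.05. The smallest adjusted p was 0.0817, for miR-145a-3p, which was 0.680-fold in 14-day sham relative to 7-day sham (log2 fold change -0.55 ± 0.13 SE). edgeR and DESeq2 each called 1, miR-145a-3p, and limma-voom called 0. Without 7-day sham replicate 3, limma called miR-145a-3p as well. Of 20 lists, camera with an estimated correlation called 0 and fry 0. With a preset correlation 2 passed in 14-day sham against 7-day sham. They were the Dlk1-Dio3 cluster, with 45 of 58 members below 0 (camera adjusted p = 0.00261), and the miR-30 family, with 9 of 9 above 0 (camera adjusted p = 0.0477). Each ran opposite to its 14-day Ang II effect, but both comparisons use the 14-day sham group, with opposite sign. Spread in that group alone pushes them in opposite directions, so no conclusion is drawn from this.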

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

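The tests of the Dlk1-Dio3 cluster with a class term and with a mouse-number term, and both tests of the library classes, were chosen only after the result was seen. Each library was compared with the others of its group of 8, for 328 groups of values. In 29 groups the highest or lowest library stood apart by more than Dixon's 95% limit. For independent, normally distributed values chance gives about 1 in 20 groups, or 16.4. RPM values were used without logarithms, and list scores overlap with their members, so an excess over chance was not shown. Of the 29, 8 were in 14-day Ang II replicate 5. By limma, and by permutation of the list scores, no miRNA or list differed between the times after adjustment.

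In 14-day Ang II replicate 5 the share of miR-143-3p was 35.28%, with the nearest other at 44.59%. There, miR-434-5p was 160.1 RPM against 85.56 for the nearest other, miR-132-3p 40.91 against 29.95, miR-298-5p 10.12 against 6.465 and miR-409-5p 4.974 against 2.534. Its score for miR-132/miR-212 was 3.442, the highest of its group, and its score for the miR-30 family was 8.52, the lowest. Novel_y_2 was lowest there with 214 RPM. In 14-day Ang II replicate 3, miR-106b-3p was 48.71 RPM and miR-93-5p 221.9 RPM, both highest. In 14-day Ang II replicate 7, miR-140-5p was highest with 137.8 RPM, and in replicate 1 the NF-kB induced score was highest with 9.061.

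In 14-day sham replicate 1, miR-21a-5p was 5874 RPM against 3782 for the nearest other, and miR-200a-5p was 28.82 against 15.85. In 14-day sham replicate 4, miR-409-5p was highest with 1.785 RPM. In 7-day sham replicate 1 the Dlk1-Dio3 score was 3.433, the neuron score 5.184 and miR-409-5p 5.045 RPM, all highest. In 7-day sham replicate 4 the red blood cell miRNAs miR-451a (976.7 RPM), miR-144-3p (119.7 RPM) and miR-486-5p/miR-3107-5p (46640 RPM) were highest. In 7-day Ang II replicate 2, miR-144-5p was 179.1 RPM, miR-144-3p 236.6 RPM and the hypoxia score 5.575, all highest. In 7-day Ang II replicate 3, miR-541-5p was highest with 545.9 RPM and the miR-23/miR-27/miR-24 score lowest with 9.057. The remaining highest values were Novel_y_47 at 29.28 RPM in 7-day sham replicate 3, miR-29a-5p at 3.031 RPM in 7-day sham replicate 5 and miR-200a-5p at 20.86 RPM in 7-day Ang II replicate 8.

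The Dlk1-Dio3 members had a median log2 fold change of 0.40 at 14 days. With a class term the median was 0.403. The nearly even split of the classes left the term little to shift, so no conclusion is drawn from it. Against the mouse-number series stands a median of 0.457 with a term for the series. Against 1 deviating library stands a median of at least 0.323, the value without 14-day Ang II replicate 5. Leaving out 1 library at a time cannot show the part of several libraries together. A change in the cell types of the artery and a change within cells, both of which Ang II may bring about, stayed open and were not tested.

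The epithelial miRNAs had a median of -0.733 at 14 days. With a class term it was -0.723, but the nearly even split of the classes left the term little to shift, so no conclusion is drawn from it. The part of 1 deviating library could not be settled, since the median was -0.52 without 14-day sham replicate 1, which kept less than the 75% set beforehand as the limit. Tissue other than artery in single sham samples may have contributed, and it cannot be told apart from an effect of Ang II on epithelial miRNAs.

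The 2 classes of libraries were found in each of the 4 groups. The axis was centred within each group, which favours this, and a shift of a whole group along it could not be seen. If differences in cell composition were the source, both strands of a hairpin should follow the axis alike, but Spearman's rho between strands was 0.09 over 114 hairpins (95% interval -0.116 to 0.276). For the 14-day Ang II effect rho between strands was 0.706, over hairpins that are not independent. Against batches that follow the mouse number stands that each series with at least 4 libraries held at least 3 of either class. The classes differed in the column totals of the deposited values, which ran from 0.727 to 1.237 M in class A and from 1.147 to 1.674 M in class B. Recovered reads over all rows ran from 14.943 to 24.556 M in class A and from 14.042 to 21.404 M in class B. The value of 1 read ran from 0.02961 to 0.07265 RPM in class A and from 0.06421 to 0.11694 RPM in class B. The higher totals of class B thus lay in the authors' scaling, and more reads are argued against. What in the libraries set that scaling was not tested. A step in library preparation may underlie the classes, but the labels give no batch to test it with. Beyond cell composition, no biological explanation was tested.

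The red blood cell miRNAs had a median of 0.988 at 14 days, 0.961 with a class term and at least 0.822 with 1 library left out (14-day sham replicate 8). The nearly even split of the classes left the class term little to shift. At 14 days miR-451a ran from 232 to 1271 RPM in sham and from 793.2 to 1627 RPM with Ang II. Whether these miRNAs came from red blood cells in the samples or from the artery was not tested.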

How the results depend on the processing

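The edgeR test, TMM factors, the class term, the fits to 1 class, the omission of mouse-number series 30, every row kept, and the depth over all rows were chosen only after the result was seen. The 14-day count of 35 was 23 with library totals alone, 17 with no filter, 63 with DESeq2, 16 with limma-voom and 3 with the compared groups alone. It was 80 with a class term, and 0 in each class alone by limma (107 and 105 at an unadjusted p under 0.05), where 11 and 5 libraries were left. The class came from the same values, which makes the 80 less secure. With 1 library left out the count ran from 21 (without 14-day Ang II replicate 3) to 42. It was 23 without 14-day Ang II replicate 5 or 7, or 14-day sham replicate 5 or 8. The average effect's 40 was 23 with library totals alone, 68 with DESeq2, 129 with a class term, 12 in class A and 0 in class B, and 30 to 52 with 1 library left out. The 7-day count of 1 was 10 with limma-voom. It was 0 with library totals alone, with the compared groups alone and in class A (18, 48 and 60 at an unadjusted p under 0.05). With 1 library left out it ran from 0 to 1. It was 0 without 7-day sham replicate 2, 5, 6, 7 or 8, or 7-day Ang II replicate 1, 2, 3, 4 or 5. The sham comparison's 0 was 1 with a mean of at least 10, DESeq2, the compared groups alone, edgeR (each miR-145a-3p) and the mouse-number term (Novel_z_8). With 1 library left out it ran from 0 to 1, the latter without 7-day sham replicate 3. The interaction gave 0 in all 16 settings and 32 fits with a library left out. The list counts of 0 were 7 with a preset correlation at each time, and 8 with fry at 14 days. The 14-day depth difference of 1.56 M was 3.06 M over all rows (exact permutation p = 0.0452). For lower counts in fewer libraries the cause may be the smaller number, as in the fits to 1 class (0), and for the other settings the cause was not tested.

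Directions reversed as follows, all for values that did not pass, and the cause was not tested. With library totals alone the 14-day medians were 0.154 for contractile smooth muscle, 0.05 for striated muscle, 0.035 for the miR-29 family and 0.194 for the miR-23/miR-27/miR-24 clusters. So were miR-145a-3p (0.154), miR-145a-5p (0.256) and miR-126-3p (0.147). The adipose median was 0.111 with a class term at 7 days. At 14 days it was -0.094 with the mouse-number term, -0.082 with a class term and -0.005 with a pseudocount of 10. The miR-322/miR-503 median was -0.002 with a pseudocount of 10 at 7 days. At 14 days it was -0.034 with the mouse-number term, -0.066 with a class term, -0.005 with a pseudocount of 10 and -0.029 with no filter. The let-7 median at 14 days was -0.066 with the mouse-number term and -0.032 with a class term. For miR-143-3p at 7 days the values were 0.009 (library totals), 0.001 (DESeq2), 0.179 (limma-voom), 0.002 (mouse-number term) and 0.018 (edgeR), and -0.121 to 0.057 with 1 library left out. For miR-155-5p at 7 days they were -0.044 (limma-voom) and -0.004 to 0.117 with 1 library left out. For miR-145a-5p at 14 days they were 0.027 (DESeq2), 0.111 (limma-voom), 0.027 (edgeR), 0.057 (class A) and -0.101 to 0.09 with 1 library left out.

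Over all settings, the values of the named miRNAs kept direction and side of the threshold 2564 times, lost the call 290 times, gained it 49 times and reversed 25 times. Of the named 14-day calls, those that passed in 16 of 16 fits that left out a library were miR-434-5p, miR-431-5p, miR-337-5p, miR-132-3p, miR-541-5p, miR-140-3p, miR-411-5p, miR-203-3p, miR-382-5p, miR-199a-5p and miR-96-5p. The fewest fits were passed by miR-26b-5p (3 of 16), Novel_y_30 (4), miR-144-5p and miR-300-3p (5 each), miR-708-3p (6), miR-181c-5p (8), and miR-101a-3p and miR-101c (9 each). miR-451a lost its call without sham replicate 6, 7 or 8 or Ang II replicate 3, and miR-106b-3p without Ang II replicate 3. miR-140-5p lost it without sham replicate 5 or Ang II replicate 7, and miR-212-3p without sham replicate 7 or 8 or Ang II replicate 1 or 5. Novel_y_2 lost it without sham replicate 7 or Ang II replicate 3 or 5, and Novel_y_47 without sham replicate 2 or 5 or Ang II replicate 8. The correlation of the 7-day and 14-day effects ran from 0.214 to 0.484 over its other settings, and from 0.074 to 0.364 with 1 library left out. No paired analysis was possible because the replicate numbers follow the order of the samples and the labels number no replicates that link a sham mouse with an Ang II mouse. The median SE of a log2 fold change was 0.181, which limited what could be seen: in simulated data 38% of 1.5-fold and 82% of 2-fold changes were recovered. The simulation changed 200 of 543 miRNAs, drew each independently and made 118 calls, against 35 in the real 14-day comparison. Its rates may therefore overstate the sensitivity of the real comparisons.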

Other observations

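The miRNAs named in the next sentences and the split test with a class term were chosen only after the result was seen. Some miRNAs outside the rule for the average effect changed on average over both times. miR-96-5p fell to 0.670-fold (log2 fold change -0.58 ± 0.13 SE, limma adjusted p = 0.00816) and miR-30c-5p to 0.809-fold (adjusted p = 0.0222). miR-145a-3p fell to 0.779-fold (adjusted p = 0.0138), from a log2 fold change of -0.60 at 7 days and -0.12 at 14 days (adjusted p = 0.598). miR-511-3p, which lies in an intron of a macrophage receptor gene, rose 1.24-fold (adjusted p = 0.0207). miR-298-5p rose 1.39-fold (adjusted p = 0.0112) and miR-125b-1-3p 1.22-fold (adjusted p = 0.0182). These 6 passed without each of the 32 libraries in turn, but each lost its call in other settings. Within class B alone none of the 6 passed, and within class A alone miR-145a-3p was the only one that did. With library totals alone miR-30c-5p (log2 fold change -0.15, adjusted p = 0.686), miR-145a-3p (-0.20, adjusted p = 0.491) and miR-96-5p (-0.43, adjusted p = 0.0521) did not pass.

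Other splits of the same libraries were drawn at random, 100 per comparison with the real one included. For the 14-day comparison the real split alone, 1 of 100, gave as many as 35 calls, and the highest other gave 14. Chance is thus an unlikely source, though 100 splits cannot show a share below 1 of 100. For the average effect 1 of 100 gave as many as 40, the highest other 0, with the same reading. With a class term, 1 of 100 splits within the classes gave as many as 80 at 14 days, the highest other 19. The classes came from values centred on the real groups and were kept for every split. That may favour the real split, so no conclusion is drawn from this count. For the 7-day comparison 5 of 100 gave as many as 1 call, the highest other 5, so chance cannot be excluded. For the interaction and the sham comparison, where limma called 0 (25 and 18 at an unadjusted p under 0.05), 100 of 100 splits gave as many, the highest other 1. The list counts of 0 at 7 and at 14 days were also met by 100 of 100, the highest other 1. A count of 0 is met by every split, so these results were fixed in advance and say nothing about chance.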
